A study of Homo sapiens with 22 samples.

How the data were processed

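Messenger RNA from 22 formalin-fixed, paraffin-embedded primary cutaneous melanomas was measured with the nCounter Tumor Signaling 360 panel, a hybridisation assay in which each target molecule is counted through a coloured barcode without amplification. Per the labels, 14 tumours had histological ulceration and 8 did not. RNA was isolated from thick tissue scrolls with a kit for fixed tissue, and the input was set by the share of long RNA fragments, per the labels' protocols.

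The deposited table held whole numbers for 780 gene probes, 8 negative control probes and 6 positive control probes in each sample. The deposited values were treated as a score and not as raw molecule counts. The reason is in the values: the 6 positive control probes summed to 18466 or 18467 in 11 samples (lane set 1) and to 16192 or 16193 in the other 11 (lane set 2). The values had therefore been scaled within each of 2 sets of lanes and rounded. The software that did this and any background step are not given in the sources used here. No scaling to housekeeping genes or to total signal was visible in the deposited values. Each lane set held 7 ulcerated and 4 non-ulcerated tumours, and is treated below as a technical batch. The labels give no batch.

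The sum over gene probes ranged from 185998 to 384580 in 21 samples. In 1 ulcerated sample it was 12993, which was 19.2-fold below the median of the others. A gene was taken as above background where its value exceeded the mean plus 2 SDs of the negative controls of that sample. Between 639 and 757 genes were above background in the 21 samples, against 379 genes (48.6%) in the weak sample. The weak sample stayed in the comparison, and each leading count was also computed without it. The 8 non-ulcerated tumours limit the precision of every difference.

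Gene symbols were used as the deposited table gives them. A gene name table listed 773 of the 780 symbols, and the other 7 were older names or probes shared by near-identical genes. No genome or coordinates were used.

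Values were transformed as log2(value + 1). Each sample was then centred on the mean of 17 housekeeping genes from a list fixed in advance. The planned test had named no centring for values of this kind, and centring was chosen after the table was seen but before any comparison of the groups. Differences are on the log2(value + 1) scale, where the added 1 shrinks changes of genes near background. In the weak sample centring works the other way. It raised values near background there, which lifts the ulcerated mean of low genes. Ulcerated and non-ulcerated tumours were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), without covariates, over all 780 genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05.

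The tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 15 genes in each direction past the threshold. Where fewer than 10 passed, it took the 10 genes of smallest p. It added, per list, up to 4 members that passed or else the member of smallest p. A gene that the rule names is not reported here. The 22 lists covered keratinocyte, melanocyte, neutrophil, T and NK, B and plasma, macrophage, and dendritic and mast cell markers. They also covered interferon gamma and type I interferon responses, hypoxia, oxidative phosphorylation, cell cycle, DNA damage repair, extracellular matrix, angiogenesis, MAPK, PI3K, WNT and Notch, NF-kB, apoptosis, chromatin regulators and heat shock. Together they held 367 panel genes.

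Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists. This test sets a list against the other panel genes, and the panel itself was chosen for tumour signalling. Camera with an estimated correlation and the directional rotation test fry were run beside it. Fry asks whether the genes of a list move on balance in a single direction, and does not set them against other genes. A list score, the mean log2 value of the members in each sample, was compared between groups by a two-sided exact permutation test over every split of the samples. Sampled permutations had been planned there, and full enumeration took their place.

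The gene test was checked on simulated data, in 10 simulations of 780 genes with 200 changed. Genes were drawn independently, with a spread taken from these samples without the weak one. The test recovered 31.0% of genes changed 1.5-fold, 52.2% at 2-fold, 84.4% at 3-fold and 92.0% at 4-fold, and 3.85% of its calls were false. With 200 genes changed the adjusted threshold is easier to pass than where few genes change. These shares therefore do not carry over to the comparison below.

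The alternatives covered the centring, low-value filters, the pseudocount, sample weights, a rank-sum test, each sample left out in turn, the lane set, and a block for numbers that the labels share between groups. The labels do not say whether a shared number marks the same person, and this was not examined from the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.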

Results

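Expression of 780 tumour signalling genes was measured in primary cutaneous melanomas with ulceration (n = 14) and without (n = 8). Ulceration, the loss of intact epidermis over the tumour, is a microscopic feature used in melanoma staging. The median sum over gene probes was 258050 in ulcerated and 215236 in non-ulcerated tumours. A median of 713 genes was above background in ulcerated tumours and 691.5 in non-ulcerated tumours. Nothing in the labels says how the tumours were chosen, and p-values measure the spread between these samples.

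The comparison asks which genes differ in expression between ulcerated and non-ulcerated primary melanoma. S100A12, a calcium-binding alarmin of neutrophils and monocytes, was higher in ulcerated tumours by 2.51 on the log2 scale (SE 0.41, adjusted p = 0.0016). Its centred log2 value was 6.02 ± 0.90 (SD, n = 14) in ulcerated and 3.51 ± 1.07 (SD, n = 8) in non-ulcerated tumours. All 14 ulcerated tumours lay above the non-ulcerated median, and 0 of the 8 non-ulcerated tumours lay above the ulcerated median. For the weak ulcerated sample this was fixed in advance, because centring raised even a value of 0 above the non-ulcerated median. The other 13 were not so bound. S100A12 was above background in 13 ulcerated and 5 non-ulcerated tumours, and near background the size depends on the scale (1.93 with a pseudocount of 10). It was the 1 gene of 780 that passed limma's test, and 0 genes were lower.

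At an unadjusted p under 0.05, limma gave 73 genes, of which 67 were higher and 6 lower in ulcerated tumours. An exact rank-sum test gave 0 genes after adjustment and 68 before it, with an adjusted p of 0.0585 for S100A12. The median difference over all 780 genes was 0.16 with housekeeping centring (0.08 without the weak sample) and -0.04 with each sample centred on its median gene. List medians below are therefore read against 0.16. With the latter centring, 40 genes were higher and 29 lower at an unadjusted p under 0.05, and quantile normalization gave 33 and 18. S100A12 differed by 2.23 in lane set 1, where it did not pass (adjusted p = 0.695), and by 2.78 in lane set 2. With the lane set as a block its adjusted p was 0.0020, and without the weak sample it was 0.0037.

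**Figure D1:**
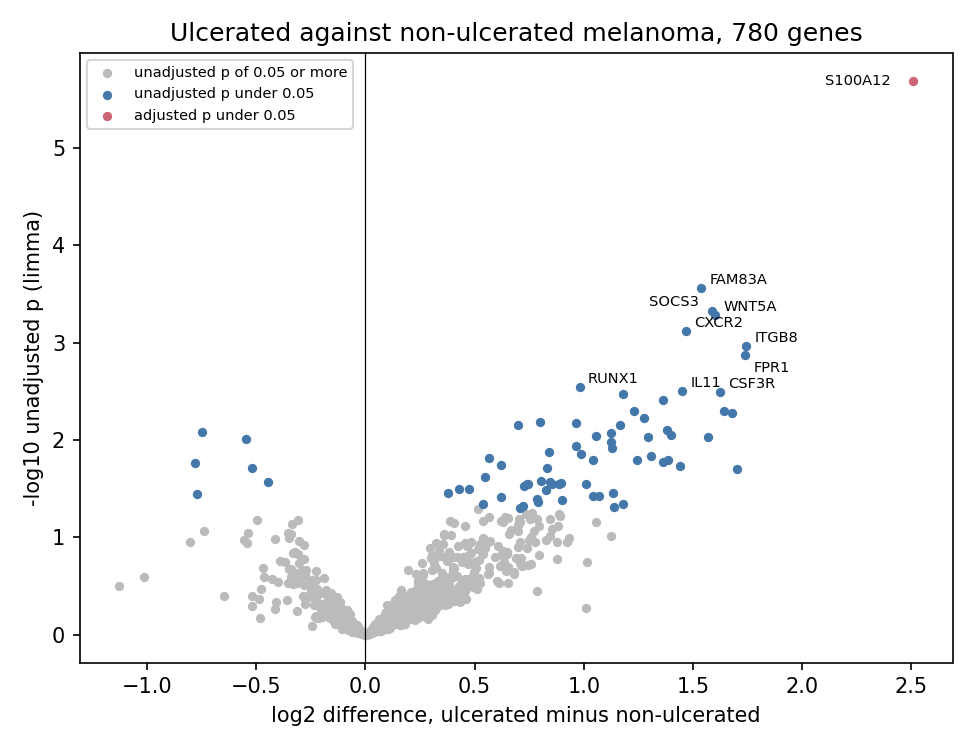
Each point is a gene, with the log2 difference (ulcerated minus non-ulcerated) on the horizontal axis and -log10 of limma's unadjusted p on the vertical axis. S100A12, at 2.51, is the 1 gene past the adjusted threshold, and 67 of the 73 genes with an unadjusted p under 0.05 lie to the right of 0 under housekeeping centring.

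The other 9 genes of smallest p did not pass. FAM83A, an adaptor of EGFR and RAS signalling, differed by 1.54 (SE 0.37), SOCS3, a feedback inhibitor of STAT3 signalling, by 1.59 (SE 0.40), and WNT5A, a non-canonical WNT ligand, by 1.60 (SE 0.40), each with an adjusted p of 0.102. The integrin subunit ITGB8 differed by 1.74 (SE 0.47, adjusted p = 0.141). The transcription factor RUNX1 differed by 0.98 (SE 0.30) and the cytokine IL11 by 1.45 (SE 0.45), both with an adjusted p of 0.240. FAM83A had a difference of 0.62 in lane set 1 and 2.45 in lane set 2.

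Neutrophil and acute inflammation genes had the highest median of the 22 lists. The median difference of the 18 measured members was 0.91, and 17 of them had a difference above 0. Over all genes 1 member rose, S100A12, 0 fell and 17 did not pass; adjusted over the list alone, 10 were higher and 0 lower. Members that did not pass over all genes included the chemokine receptor CXCR2 (1.47, SE 0.39), the formyl peptide receptor FPR1 (1.74, SE 0.48) and the granulocyte growth factor receptor CSF3R (1.62, SE 0.50). Their adjusted p-values were 0.118, 0.150 and 0.240. The list was shifted up against the other panel genes at the preset correlation (adjusted p = 1.9e-07), and was not with an estimated correlation (adjusted p = 0.711 with an estimated correlation). The estimate for this list was 0.433, far above the preset of 0.01. The list score was 1.02 higher in ulcerated tumours (exact permutation p = 0.0058, adjusted p = 0.117 over the 22 lists), with 14 of 14 ulcerated tumours above the non-ulcerated median. Centring raised the weak sample's near-background values in this score, so only the other 13 tumours inform that count. Without the weak sample the difference was 0.95. The score was 0.86 higher within lane set 1 and 1.18 within lane set 2 (1.01 there without the weak sample).

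**Figure D2:**
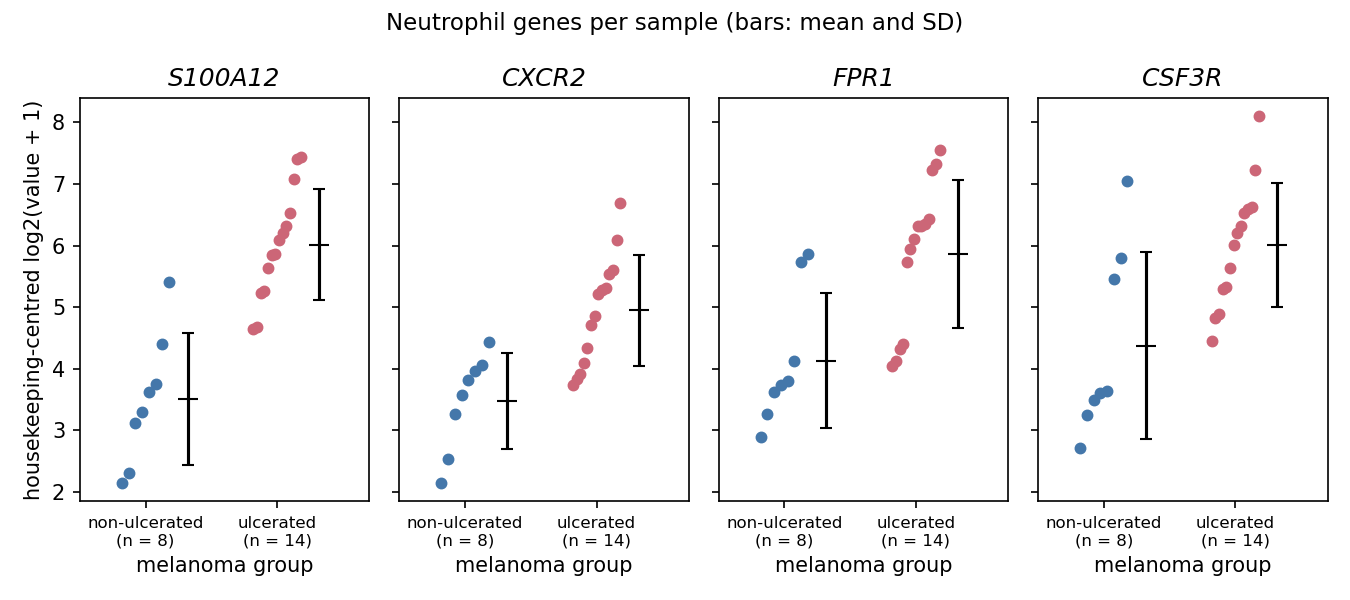
Each point is a tumour's housekeeping-centred log2(value + 1) of S100A12, CXCR2, FPR1 or CSF3R, in 8 non-ulcerated and 14 ulcerated tumours sorted by value, with mean and SD as bars. S100A12 ranged from 4.65 to 7.44 in ulcerated and from 2.15 to 5.41 in non-ulcerated tumours, while CSF3R overlapped more, with 2.72 to 7.04 in non-ulcerated tumours. The weak sample is among the ulcerated points, and centring raised its values, which were near background for these genes.

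Extracellular matrix and mesenchymal genes were the next list. Their 27 members had a median difference of 0.63, with 24 above 0, and the list passed at the preset correlation (adjusted p = 1.0e-04). It did not pass with an estimated correlation (adjusted p = 0.711 with an estimated correlation), which was 0.278 for this list. No member passed over all genes (0 higher, 0 lower) and 0 did adjusted over the list alone. The member of smallest p was INHBA, which encodes the activin A subunit, with a difference of 1.23 (SE 0.40, adjusted p = 0.270). The list score was 0.57 higher (exact permutation p = 0.0106, adjusted p = 0.117), with 0.47 in lane set 1 and 0.67 in lane set 2.

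Keratinocyte and epidermis markers had a median difference of 0.63 over 13 members, 12 of them above 0. The list passed at the preset correlation (adjusted p = 0.016) and not with an estimated correlation (adjusted p = 0.711 with an estimated correlation). Singly, 0 members passed over all genes and 0 adjusted over the list alone, where leaving out the weak sample gave 4 higher. The list score was 0.67 higher (exact permutation p = 0.0603, adjusted p = 0.266), with 0.35 in lane set 1, where the list did not pass (adjusted p = 0.890), and 1.00 in lane set 2. The call was also lost in 3 of the 22 fits that left out a single sample (highest adjusted p = 0.0877).

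DNA damage repair genes were the 1 list shifted down against the panel at the preset correlation (adjusted p = 0.020), which was lost with an estimated correlation (adjusted p = 0.711 with an estimated correlation). Their median difference was -0.04 over 26 members, which lies below the 0.16 of all genes and close to 0. PARP1, a sensor of DNA strand breaks, differed by -0.35 (SE 0.21, adjusted p = 0.666), and 0 members passed over all genes or adjusted over the list alone. The difference in list score was -0.03 (exact permutation p = 0.852, adjusted p = 0.938), with 0.22 in lane set 1 and -0.28 in lane set 2. The call was also lost without the lowest 25% of genes (adjusted p = 0.0677), in lane set 1 (adjusted p = 0.429) and in 6 of the 22 fits that left out a single sample (highest adjusted p = 0.270).

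**Figure D3:**
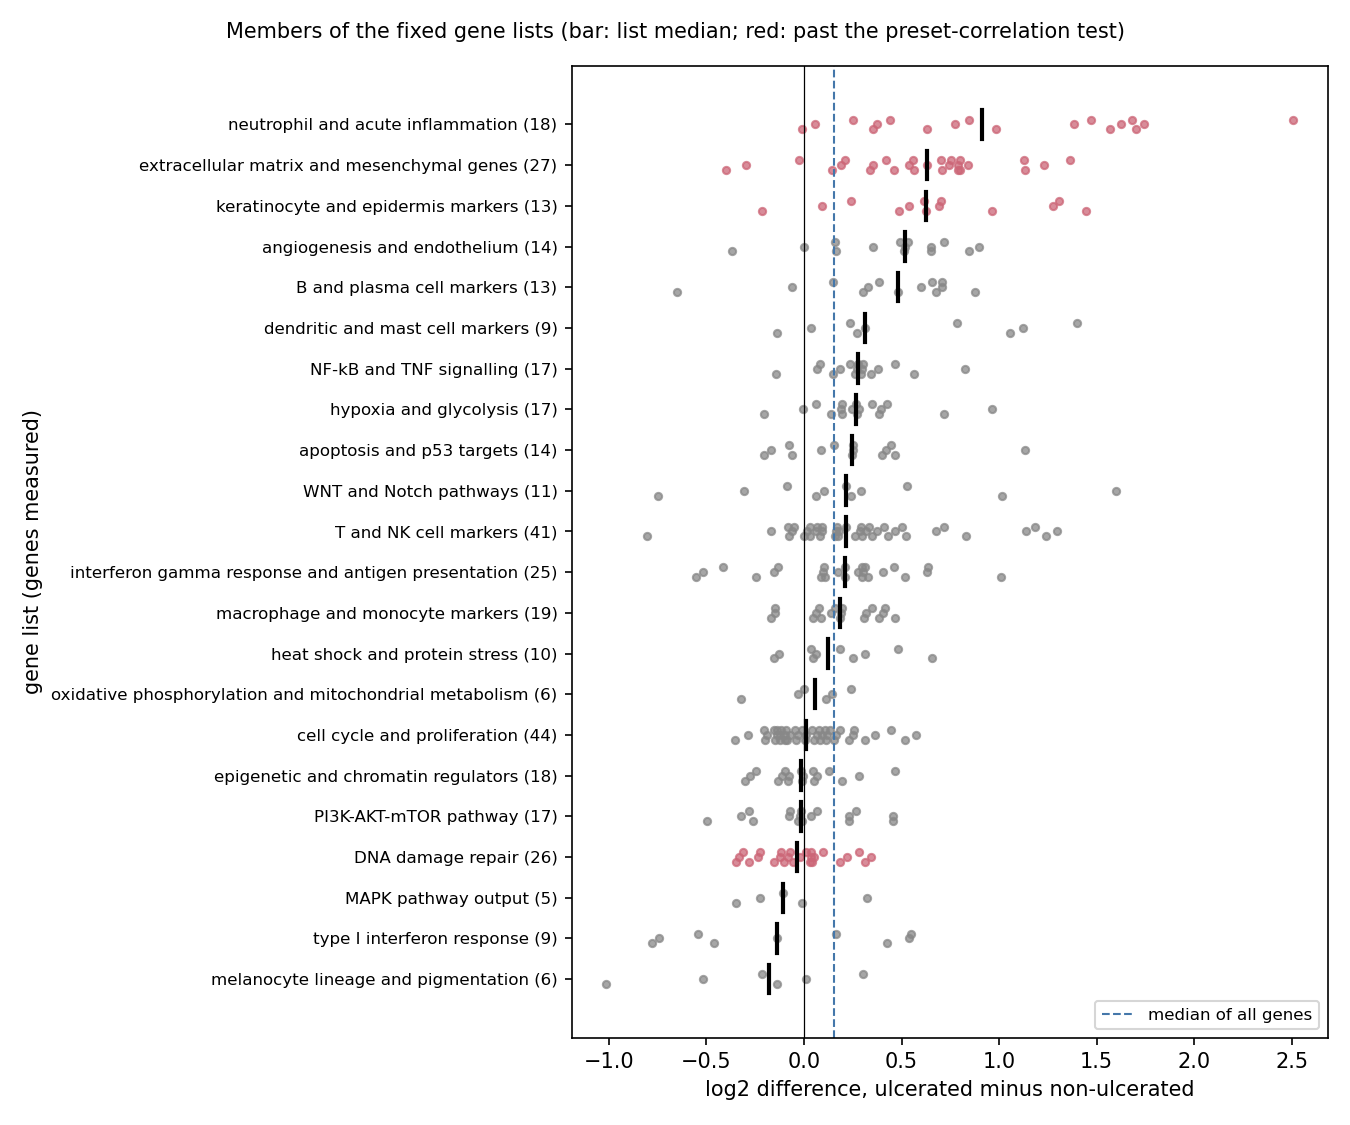
Each point is a measured member of a fixed gene list, placed by its log2 difference (ulcerated minus non-ulcerated, housekeeping centring), with the list median as a bar and the median of all genes as a dashed line at 0.16. The neutrophil list has the highest median, 0.91, and the melanocyte list the lowest, -0.18.

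Markers of other leukocytes did not pass the list test. T and NK cell markers had a median difference of 0.21 over 41 genes (adjusted p = 0.793), macrophage and monocyte markers 0.18 over 19 (adjusted p = 0.956), and B and plasma cell markers 0.48 over 13 (adjusted p = 0.398). The macrophage list's median lay above 0 while its test pointed down. Dendritic and mast cell markers had a median of 0.31 over 9 genes (adjusted p = 0.375). In lane set 2 alone this list was called up at the preset correlation, with or without the weak sample. Its score differed by 1.09 there and by 0.04 in lane set 1. Without the weak sample these medians were lower: T and NK 0.06, macrophage 0.10, B and plasma 0.32, dendritic and mast cell 0.24. The median of all genes was then 0.08. In these 4 lists 0 members passed over all genes, and 0 did adjusted over the list alone. The members of smallest p were the interleukin 7 receptor IL7R (1.18, SE 0.37), the lipopolysaccharide receptor TLR4 (0.47, SE 0.29), the plasma cell proteoglycan SDC1 (0.71, SE 0.37) and the mast cell IgE receptor chain MS4A2 (1.40, SE 0.50). SDC1 is also made by keratinocytes, and MS4A2 was above background in 9 ulcerated and 2 non-ulcerated tumours.

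Melanocyte lineage genes had a median difference of -0.18 over 6 members (adjusted p = 0.140), and 0 passed over all genes or adjusted over the list alone. Leaving out 1 non-ulcerated sample had this list called down at the preset correlation. MLANA, a melanosomal antigen, had a difference of -1.01 (SE 0.87, adjusted p = 0.837). Its log2 value was 10.75 ± 2.66 (SD, n = 14) in ulcerated and 11.76 ± 0.89 (SD, n = 8) in non-ulcerated tumours. Angiogenesis and endothelial genes had a median of 0.52 over 14 members (adjusted p = 0.135), and VWF, a clotting protein of endothelium, differed by 0.90 (SE 0.38, adjusted p = 0.405).

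Immune signalling lists did not pass the list test. The interferon gamma and antigen presentation list had a median of 0.21 over 25 genes (adjusted p = 0.969), with a difference of 0.64 (SE 0.33) for SOCS1, an inhibitor of interferon signalling. The type I interferon list had a median of -0.14 over 9 genes (adjusted p = 0.280). Its member OAS3, an antiviral enzyme, differed by -0.78 (SE 0.31, adjusted p = 0.336), with 0 of 14 ulcerated tumours above the non-ulcerated median. NF-kB and TNF signalling genes had a median of 0.28 over 17 genes (adjusted p = 0.295), with 0.83 (SE 0.37) for the adaptor TRAF1. Without the weak sample the NF-kB median was 0.16, against 0.08 for all genes.

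Metabolic, proliferative and stress lists did not pass it either. Hypoxia and glycolysis genes had a median of 0.27 over 17 members (adjusted p = 0.229), and ADM, the hypoxia-responsive peptide adrenomedullin, differed by 0.96 (SE 0.33, adjusted p = 0.270). Oxidative phosphorylation genes had a median of 0.06 over 6 members (adjusted p = 0.474), with -0.32 (SE 0.21) for IDH1. The member SDHA is also among the 17 housekeeping genes used for centring. Cell cycle genes had a median of 0.01 over 44 members (adjusted p = 0.129), and the mitotic kinase AURKA differed by 0.52 (SE 0.25, adjusted p = 0.544). At the preset correlation the cell cycle list was called down in lane set 2. It was also called down in a few fits that left out a single sample, as without 1 ulcerated sample (adjusted p = 0.0088). Heat shock genes had a median of 0.12 over 10 members (adjusted p = 0.956), with 0.66 (SE 0.38) for the haem-degrading enzyme HMOX1. Apoptosis and p53 target genes had a median of 0.25 over 14 members (adjusted p = 0.956), with 1.13 (SE 0.51) for the matrix glycoprotein THBS1. The apoptosis median was 0.09 without the weak sample.

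Of the pathway lists, MAPK output genes had a median of -0.11 over 5 members (adjusted p = 0.253), with -0.35 (SE 0.27) for MYC. PI3K-AKT-mTOR genes had a median of -0.01 over 17 (adjusted p = 0.209), with -0.50 (SE 0.26) for the leukocyte kinase PIK3CD. In lane set 2 alone this list was called down at the preset correlation, with or without the weak sample. Chromatin regulators had a median of -0.01 over 18 (adjusted p = 0.129, or 0.0123 and shifted down with median centring), with -0.30 (SE 0.18) for the histone methyltransferase SETD2. WNT and Notch genes had a median of 0.22 over 11 (adjusted p = 0.956), or 0.11 without the weak sample. In that list 1 gene was higher and 1 lower adjusted over the list alone, WNT5A and CTNNB1, the latter at -0.75 (SE 0.26) named after its value was seen and not passing without the weak sample. In the angiogenesis, immune signalling, metabolic, stress and other pathway lists, 0 genes passed adjusted over the list alone. In these lists and the WNT and Notch list, 0 genes passed over all genes.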

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

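Of the tests below, those of the weak sample, of scaling, of leukocytes in general, of the farthest list and of the share of higher genes were chosen after the result was seen. The gap test covered 53 measures in the 8 non-ulcerated tumours.

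For 6 of 53 measures 1 non-ulcerated tumour lay apart from the other 7, where about 2.65 are flagged by chance at 1 in 20. Which tumour lay apart was not recorded, so it need not be the same for all 6. The measures overlap, so 2.65 is only a rough guide. The gap over the whole range was 0.642 for SDC1, 0.574 for IDH1 and 0.540 for the keratinocyte list score, each with the highest tumour apart. It was 0.565 for PARP1 and 0.690 for the melanocyte list score, each with the lowest apart. For the sum over gene probes it was 0.583, with the highest apart.

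The higher neutrophil list in ulcerated melanoma was set against chance first. Of 100 splits of the 22 tumours, the real one included, 13 gave some list whose median lay as far from that of all genes (0.759 in the real split, 1.26 in the highest other), so chance cannot be excluded. The weak sample is argued against by a list median of 0.849 without it, and the lane sets by a smaller within-set score difference of 0.859. For scaling, the list median minus that of all genes was used, which a constant per sample cannot move. Scaling before the pseudocount differs from such a constant only through the added 1, so its 0.658 says little. Quantile normalization is not a constant per sample. It left 0.592 (0.706 without the weak sample), which argues against scaling as the source. More leukocytes of every kind stay open. The neutrophil score differed by 0.731 more than the mean of the T and NK, B and macrophage scores (exact permutation p = 0.0292). This contrast was higher in 14 of 14 ulcerated tumours than the non-ulcerated median. Many values of the weak sample lay near background, so only the other 13 tumours inform that count. Without the weak sample the contrast differed by 0.800. However, the neutrophil list was picked as the highest of 22, which favours a positive contrast, and p was not corrected for that choice. Neutrophils at the ulcer remain a hypothesis not separated from chance. The list's abundant members CCL2 and CYBB, which macrophages also make, differed by 0.055 and -0.010, the smallest differences in size among its members. The members PTGS2 and OSM differed by 1.68 and 1.39, and 17 of the 18 genes lay above 0. Which cells carried the transcripts of the list was not tested (0 of its 18 genes are in another list).

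The numbers of calls were set against the same 100 splits. As many as 4 shifted lists came from 75 of 100 splits (10 in the highest other), so chance cannot be excluded for the calls at the preset correlation. At least 1 list was called in 97 of the other 99 splits, with a median of 5 lists. The preset correlation was therefore lenient, and repeated passes of a list under it do not separate that list from chance. As many as 1 gene higher came from 5 of 100 splits with the real one included, or 4 of the other 99 (16 in the highest other), so chance cannot be excluded for the count, and a split that calls 16 genes may point to a structure of the samples, which was tested for the lane set alone. The split by lane set gave 0 genes with limma (88 at an unadjusted p under 0.05, weak sample left out).

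Genes with an unadjusted p under 0.05 were mostly higher in ulcerated melanoma, 91.8% of 73. Centring on the median gene left 58.0% of 69 higher (50.6% of 79 without the weak sample), but such centring evens the balance by construction. Values as deposited without the weak sample gave 90.6% of 64. The mean housekeeping log2 value was then 7.94 in both groups. These values argue against housekeeping centring as the source of the imbalance in the samples other than the weak one. Which reference is right, housekeeping genes or the median gene, stays open. The weak sample is argued against: 85.3% were higher without that sample. Among genes above background in at least 8 samples the share was 91.0%. That filter kept 736 of the 780 genes and can keep genes at background in every non-ulcerated tumour. It therefore cannot decide whether values near background played a part. Leaving out the lowest 25% of genes left 88.5% of 52 higher, so the imbalance did not rest on those genes alone. A rise of many panel genes relative to housekeeping genes was not tested.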

How the results depend on the processing

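The settings with the lane set, the weak sample left out, values as deposited and scaling before the pseudocount were chosen after the data were seen. The count of 1 gene higher (S100A12) stayed at 1 with median centring, quantile normalization, both low-value filters, both pseudocounts, sample weights, the lane set as a block and without the weak sample. It was 0 with the exact rank-sum test (68 genes unadjusted), 0 in lane set 1 alone (41 unadjusted), 3 in lane set 2 alone with or without the weak sample, and 0 in values as deposited (22 unadjusted). The last is 1 again without the weak sample. Leaving out each sample in turn gave 1 to 6 genes: 4 without 1 ulcerated sample, and 6 and 2 without each of 2 non-ulcerated samples. S100A12 itself then differed by 2.31 to 2.78, with an adjusted p of 2.1e-04 to 0.0075. After adjustment 0 genes were lower in every setting run; unadjusted, limma gave 6 with housekeeping centring and from 3 (lane set 1) to 39 (median centring without the weak sample) elsewhere. With the patient number in the labels as a replicate block (not known to pair samples), with 2 residual degrees of freedom per gene and 3 shared numbers, 10 genes were higher and 6 lists shifted. S100A12 was not among the 10 (adjusted p = 0.0636), with a larger difference of 2.92 and a wider SE of 0.91. Those lists were neutrophil, extracellular matrix, keratinocyte, and WNT and Notch up, and T and NK (adjusted p = 9.4e-04) and interferon gamma (adjusted p = 0.031) down. DNA damage repair did not pass with this block (adjusted p = 0.600). Leaving out the ulcerated samples of a shared number instead gave 1 gene higher, S100A12 (2.43, limma adjusted p = 0.0084). The lists called were then those of the main fit.

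The count of 4 shifted lists was 0 with an estimated correlation and 0 with fry (which sets no list against other genes), 2 in lane set 1, 8 in lane set 2 and 7 there without the weak sample, and 3 to 6 with each sample left out. It was 5 with median centring or sample weights, where chromatin regulators joined, and 3 without the lowest 25% of genes. The neutrophil and extracellular matrix lists passed at the lenient preset correlation under each centring, filter, pseudocount, lane set and leave-one-out fit. The median of DNA damage repair turned from -0.04 to 0.0093 with a pseudocount of 10, 0.38 with the replicate block and 0.26 in lane set 1, and ran from -0.13 to 0.042 with each sample left out. The cause was not tested for any of these. Of the other comparisons, 1268 of named genes and 888 of lists kept their side of the threshold, 13 and 20 became stronger, and 4 and 6 weaker. A count model and log2 CPM had been listed before the data were seen and were not run, since the values are not counts. The weak sample had 48.6% of genes above background, so low genes could not be resolved there.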

Other observations

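The hypothesis that epidermal and neutrophil genes rise together within ulcerated tumours was stated before its test and was not borne out. Across the 13 ulcerated tumours without the weak sample, the neutrophil and keratinocyte list scores had Pearson's r = 0.0215 (permutation p = 0.944, adjusted p = 0.976 over 21 lists) and Spearman's rho = -0.0989 (permutation p = 0.751, adjusted p = 1). Without the 2 tumours farthest from the median neutrophil score r was -0.131, and within the lane sets it was 0.331 (n = 7) and -0.187 (n = 6). With median centring r was -0.113 (permutation p = 0.715). None of the 21 lists tested reached an adjusted p under 0.05 against the neutrophil score under either centring.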
